A study of Homo sapiens with 8 samples.

How the data were processed

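RNA of 8 dishes of primary human retinal endothelial cells was measured, 4 untreated and 4 treated with melphalan at 4 µg/ml for 24 h, each on 1 Affymetrix ST array. Per the labels' protocols, total RNA was extracted, its purity and integrity were checked, and 200 ng of it was made into biotin-labelled sense-strand target for whole-transcript arrays. Groups were taken from the treatment given in the labels, and no vehicle control is described. The deposited table holds log2 expression values for 33297 probe sets in 8 columns, made with the RMA method in Affymetrix Expression Console per the submitters' processing notes, which give no versions. RMA corrects each array's background, quantile-normalizes the arrays together and summarises the probes of a probe set on the log2 scale, but its settings, the array's library files and the genome build are not given in the sources used here. The column medians of 8.84 to 8.86 are near each other, as between-array normalization leaves them. The lower quartile was 7.895 to 7.901 on the treated and 7.914 to 7.935 on the untreated arrays. The upper quartile was 9.5694 to 9.5811 on the treated and 9.5554 to 9.5690 on the untreated arrays. Values were thus spread slightly wider on the treated arrays. Because the arrays were normalized together, a change in the total RNA per cell would not show, and the high level of genes these cells should not use (olfactory receptor genes, median 8.28) means that log2 differences may understate true fold changes, most of all in dim genes. No scan date or array batch is given in the sources used here, so none could be tested, and no column of another sample was used.

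Probe sets were named from a platform annotation table in which 19460 had 1 gene symbol, 1754 had several and 12083 were not listed and stay unnamed here. Symbols of 19429 of the 19460 were updated through their Entrez gene number with the gene table of assembly GRCh38.p14, and 31 kept the symbol of the annotation table. That gene table was used for names, gene type and gene length, and no coordinates are given because the value table names no genome build. Probe sets with 1 symbol covered 18417 genes; for the 769 genes with more than 1 probe set, the one with the highest mean over the 8 arrays was used. Other probe sets of CFLAR, CLSPN, PECAM1, RPL34 and KRT18 gave different values from those used.

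The deposited log2 values were used as they stand. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, group as the only term, two-sided), and genes with a Benjamini-Hochberg adjusted p below 0.05 over the 18417 genes were called. Fold changes are melphalan minus untreated on the log2 scale, with the moderated SE, and values per group are mean ± SD of 4 arrays. Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over 27 lists, of which 6 hold markers of other cell types. Camera with a correlation estimated per list and fry were run beside it. The 27 lists, the tests, the alternatives planned and the rule for the genes named were fixed before the data were examined. Of 916 listed genes 842 were measured, and the others were not analysed here. The rule named the 10 largest rises and the 10 largest falls among called protein-coding genes whose groups did not overlap, the 3 members with the smallest p in each of the 21 lists that are not marker lists, the brightest and the smallest-p member of each marker list, and 11 fixed genes (CDKN1A, MDM2, ICAM1, VCAM1, SELE, IL6, CXCL8, CCL2, PECAM1, CDH5 and VWF). Olfactory receptor genes and 6 further lists were added after the data were seen.

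The alternatives were the replicate number as a block, values quantile-normalized again, median centring, cyclic loess, leaving out the dimmest 33.3% or 50% of probe sets, eBayes with trend and robust options, array weights, the mean of a gene's probe sets, all probe sets whether named or not, an adjusted p below 0.01, a minimum change of 1.5-fold, and each array left out in turn. A fit on genes brighter than the 95th percentile of the olfactory receptor genes was added after the data were seen. Where random lists are given, 10000 were drawn, or 1000 where the olfactory receptor genes were the list set against them. After the data were seen, the olfactory receptor genes were also set against other genes in the same of 50 bins of mean level. The scripts were tested on simulated data for this comparison with 18417 genes, of which 200 were changed. The test recovered 7.5% of the genes changed by 0.1 on the log2 scale, 55% of those changed by 0.2, 77.5% of those changed by 0.3 and 100% of those changed by 0.5 or 1. It made 143 calls of which 7 were false, and of the 27 lists only the one with an added change of 0.2 was called. The simulated genes varied independently of each other, whereas the correlation estimated for the interferon-stimulated genes in the real data was 0.24. The simulation therefore cannot show how the list test behaves on correlated genes.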

Results

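Gene expression was measured on 8 Affymetrix whole-transcript (ST) arrays of primary human retinal endothelial cells, the cells that line the small vessels of the retina. The cells were grown to 90% confluence, and 4 dishes were left untreated while 4 received melphalan at 4 µg/ml for 24 h, with 1 array per dish. Melphalan is a nitrogen mustard that alkylates DNA and links its strands, and it is infused into the artery of the eye to treat retinoblastoma, which exposes the retinal vessels to it. The deposited values were log2 RMA expression values, and the array medians lay between 8.84 and 8.86. Correlations between arrays of 1 group were 0.993 to 0.996 and those between groups 0.988 to 0.995. The median SD of a gene was 0.0535 among the untreated and 0.0520 among the treated arrays. The first principal component held 50.9% of the variance and had all 4 untreated arrays on one side and all 4 treated arrays on the other. The labels do not say whether the dishes came from separate cultures or donors, so the p-values measure the spread between these dishes, and the number of arrays limits the precision.

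The comparison asks what melphalan changed in these cells after 24 h. The largest rises were in interferon-stimulated genes, in PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, and in ADAMTS1, a secreted protease that cleaves proteoglycans. IFI44 (probe set 7902553), an interferon-induced gene, went from 7.67 ± 0.07 to 9.43 ± 0.30 (mean ± SD, log2, n = 4 each), a rise of 1.76 (SE 0.12) or 3.39-fold with limma adjusted p = 1.32e-05. PTGS2 (probe set 7922976) rose by 1.37 (SE 0.07), which is 2.59-fold, from 9.86 ± 0.08 to 11.24 ± 0.14 (adjusted p = 2.73e-06), and ADAMTS1 rose by 1.05 (SE 0.08, adjusted p = 3.71e-05). ICAM1, which binds leukocyte integrins, rose by 0.75 (SE 0.06) from 9.64 ± 0.08 to 10.39 ± 0.13, and CXCL8, a chemokine that draws neutrophils, rose by 0.85 (SE 0.07) from 9.69 ± 0.18 to 10.54 ± 0.06. TNFRSF10D, a decoy receptor for the death ligand TRAIL, fell by 0.48 (SE 0.04) from 10.75 ± 0.05 to 10.27 ± 0.08, and ALDH1A1, a retinaldehyde dehydrogenase, fell by 0.39 (SE 0.06) from 11.23 ± 0.06 to 10.84 ± 0.12.

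Across the 18417 genes tested, limma with Benjamini-Hochberg adjustment called 1211 higher and 447 lower after melphalan at adjusted p below 0.05. Most of these changes were small: 37 genes were at least 1.5-fold higher, 10 of them at least 2-fold, and the 1 gene at least 1.5-fold lower was SNORD13P1, a small nucleolar RNA pseudogene named only after its values were seen (log2 change −0.75, SE 0.10). The groups did not overlap in 3225 genes, 17.5% of those tested, where chance gives 2.86%, and 1564 of the 1658 called genes were among them. The 10 genes with the largest rises were IFI44, IFI44L (1.71), PTGS2, IFIT1 (1.20), MX1 (1.09), DDX60L (1.08), SAMD9 (1.06), ADAMTS1, RIGI (1.04) and SAMD9L (1.01). Among protein-coding genes with non-overlapping groups the 10 largest falls were in SESN3 (−0.56), GDF3 (−0.53), ZNF578 (−0.51), FABP4 (−0.49), TNFRSF10D, KLRG1 (−0.45), SELENOP (−0.42), ALDH1A1, MYH10 (−0.38) and FBN1 (−0.37). SESN3 encodes a stress-regulated sestrin, FABP4 a fatty acid binding protein and MYH10 a non-muscle myosin heavy chain.

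Of the 447 genes called lower, 340 were dim. Olfactory receptor genes, which endothelial cells are not known to use, had a median level of 8.28 with a 95th percentile of 9.28, and 39 of the 338 were called lower and 0 higher (median log2 change −0.08, and −0.05 under cyclic loess, against −0.02 for all genes). That count of 39 fell to 14 without untreated 1, 19 without untreated 2, 18 without melphalan 1 and 19 without melphalan 3. It was 17 with the replicate number as a block, 19 when values were quantile-normalized again and 13 under cyclic loess. Without the dimmest 33.3% and 50% of probe sets, where fewer were tested, it was 23 and 10, and with array weights it was 59. By limma, 7366 genes were brighter than that percentile, with 773 higher and 107 lower, and the dimmer genes had 438 higher and those 340 lower. Tested alone, a choice made after seeing the data, the 7366 brighter genes gave 971 higher and 174 lower. SESN3, GDF3, ZNF578, KLRG1 and SELENOP lay in the dim range, while FABP4, TNFRSF10D, ALDH1A1, MYH10 and FBN1 lay above it. Of the 10 largest rises IFI44, SAMD9 and DDX60L lay in the dim range. So did CXCL11, IL6, SELE, SOD2, PSAT1, NR4A2, PMAIP1 and LYVE1, among other genes named below. The untreated mean of IFI44, 7.67, was below the olfactory receptor median, so the size of its rise is uncertain. SELENOP lost its call without untreated 1 or 2 or melphalan 1, 2 or 3 (adjusted p from 0.0578 to 0.0826). The number of changed genes was 989 without untreated 1, 858 without untreated 2 and 934 without melphalan 1. The number lower was 230, 184 and 226 without these arrays in turn, and 247 without melphalan 3 and 267 without melphalan 4; the number higher was 759, 674 and 708 without untreated 1, untreated 2 and melphalan 1.

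**Figure D1:**
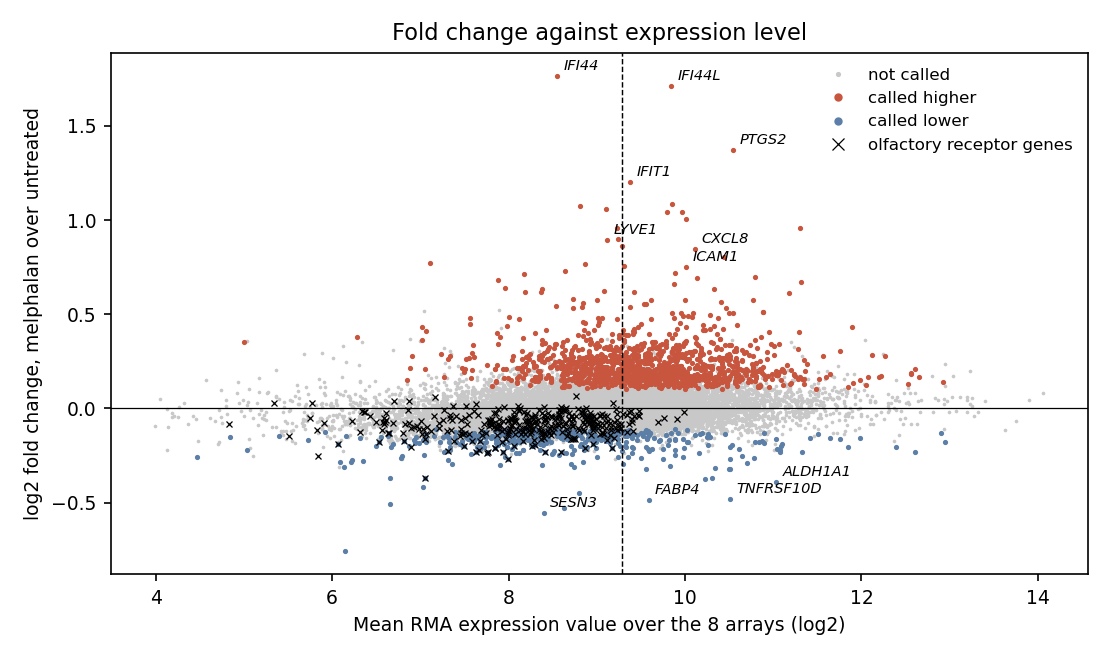
Log2 fold change of each gene (melphalan over untreated, vertical axis) against its mean log2 RMA value over the 8 arrays (horizontal axis), with genes called higher in red, genes called lower in blue and crosses for the 338 olfactory receptor genes. The dashed line marks the 95th percentile of the olfactory receptor genes, 9.28; the largest rise is IFI44 at 1.76, and most crosses lie below 0, with a median of −0.08.

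Interferon-stimulated genes formed the group with the largest shift: 34 of the 44 measured rose, 0 fell and 10 did not pass the test, with a median log2 change of 0.45 (37 higher and 0 lower when adjusted over the list alone). IFI44L rose by 1.71 (SE 0.09) from 8.98 ± 0.16 to 10.70 ± 0.19. IFIT1, which binds foreign RNA by its cap, rose by 1.20 (SE 0.10) from 8.78 ± 0.05 to 9.98 ± 0.26, MX1, a GTPase that restricts viruses, rose by 1.09 (SE 0.09), and RIGI, a sensor of double-stranded RNA, rose by 1.04 (SE 0.07) from 9.28 ± 0.05 to 10.32 ± 0.18. CXCL11, an interferon-induced chemokine for T cells, rose by 0.64 (SE 0.08) from 7.64 ± 0.12 to 8.28 ± 0.17. Its untreated mean also lay below the olfactory receptor median, so the size of its rise is uncertain. The list was called higher by camera with a preset correlation of 0.01 (adjusted p = 4.7e-35). It was not called with an estimated correlation (adjusted p = 0.105), and none of the 27 lists was. The leukocyte markers, whose cells also carry interferon responses, had a median of −0.08 with 0 of 14 called in either direction.

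Lists of inflammation and leukocyte adhesion genes were called higher with the preset correlation but not with an estimated one, and most of their members were not called. In the list of NF-kB targets and feedback, 6 of 24 rose, 1 fell and 17 did not pass (median 0.06, and 0.04 without untreated 3; 7 higher and 1 lower over the list alone). PTGS2 led it, followed by SOD2, the mitochondrial superoxide dismutase (0.26, SE 0.04), and NFKBIB, an inhibitor of NF-kB (0.17, SE 0.03), and the member that fell, named after its values were seen, was IER3 (−0.23, SE 0.06). For this list camera returned adjusted p = 0.000782 and, with an estimated correlation, adjusted p = 0.202. Of 35 cytokines and chemokines 8 rose, 0 fell and 27 did not pass (9 higher and 0 lower over the list alone), among them CXCL8, CXCL11 and IL6, an inflammatory cytokine that rose by 0.40 (SE 0.05) from 8.70 ± 0.03 to 9.10 ± 0.12. The median of this list was 0.00608, but −0.00251 without untreated 3, −0.00272 without melphalan 2 and 0.0172 without melphalan 4. For the cytokines camera gave adjusted p = 0.04999, and adjusted p = 0.339 with an estimated correlation. CCL2, a monocyte chemokine, differed by 0.16 (SE 0.06, adjusted p = 0.104) and was not called, but passed without melphalan 2 (0.20, adjusted p = 0.0371). Of 30 genes of leukocyte adhesion 7 rose, 0 fell and 23 did not pass (7 higher and 2 lower over the list alone; median 0.0224, and 0.0341 without untreated 3 or 4), with camera adjusted p = 0.00839 and adjusted p = 0.277 with an estimated correlation. Besides ICAM1 they included PODXL, a surface sialomucin (0.40, SE 0.04), CD44, the hyaluronan receptor (0.30, SE 0.03), and SELE, the endothelial selectin that slows rolling leukocytes (0.36, SE 0.06). VCAM1, the ligand of the integrin VLA-4, differed by 0.16 (SE 0.06, adjusted p = 0.128) and was not called. Beside these lists, the leukocyte markers were called lower as a list by camera (adjusted p = 0.0258), and adjusted p was 0.353 with an estimated correlation. The adhesion call was lost when values were quantile-normalized again (median 0.00338, adjusted p = 0.103), under cyclic loess (0.00810 and 0.108) and among genes above the olfactory receptor level (0.212). The cytokine call was lost under 12 alternatives besides the estimated correlation, among them leaving out untreated 3 (adjusted p = 0.0586), untreated 4 (0.145), melphalan 2 (0.0692), melphalan 3 (0.066) or melphalan 4 (0.0547).

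The ATF4, immediate early and NRF2 lists of stress responses were called higher, with members in both directions in the ATF4 and NRF2 lists. The hypoxia and glycolysis list was not called. In the list of ATF4 targets and the unfolded protein response, 15 of 36 rose, 3 fell and 18 did not pass, with a median of 0.10 (19 higher and 5 lower over the list alone). PSAT1, an enzyme of serine synthesis, rose by 0.58 (SE 0.04) from 8.45 ± 0.07 to 9.03 ± 0.03, SLC7A11, the cystine importer, by 0.61 (SE 0.06) from 10.88 ± 0.10 to 11.49 ± 0.13, and its partner chain SLC3A2 by 0.53 (SE 0.05). The 3 members that fell, named after their values were seen, were chaperones of the endoplasmic reticulum: HSP90B1 (−0.23), PDIA4 (−0.21) and CALR (−0.16). The camera test had adjusted p = 1.48e-07 for this list and adjusted p = 0.105 with an estimated correlation. Of 28 immediate early genes and feedback regulators of MAP kinases 14 rose, 0 fell and 14 did not pass (median 0.11; 14 higher and 0 lower over the list alone). DUSP1, a phosphatase of MAP kinases, rose by 0.57 (SE 0.04), NR4A2, an orphan nuclear receptor, by 0.48 (SE 0.04) and JUN, a subunit of AP-1, by 0.37 (SE 0.03). Camera gave adjusted p = 2.31e-10 and, with an estimated correlation, adjusted p = 0.105. Of 34 genes of NRF2 targets, glutathione and metallothioneins 6 rose, 2 fell and 26 did not pass (median 0.0376, and 0.0225 without untreated 4; 10 higher and 2 lower over the list alone). HMOX1, which breaks down haem, rose by 0.63 (SE 0.05) and TXNRD1, a thioredoxin reductase, by 0.42 (SE 0.06), while CAT, the catalase gene (−0.18), and GSTM4, a glutathione transferase gene (−0.14), both named after their values were seen, fell. For this list camera returned adjusted p = 0.00839 and adjusted p = 0.23 with an estimated correlation. This call was lost when values were quantile-normalized again (adjusted p = 0.0712), under cyclic loess (0.0762), without the dimmest 33.3% of probe sets (0.0566) and among genes above the olfactory receptor level (0.267). In the hypoxia and glycolysis list 5 of 29 rose, 1 fell and 23 did not pass (camera adjusted p = 0.0826; 6 higher and 2 lower over the list alone). Its median was 0.01, but −0.02 when values were quantile-normalized again, −0.00406 under cyclic loess and −0.000369 without untreated 2. NDRG1, a stress-responsive gene, rose by 0.32 (SE 0.04). ENO1, BNIP3 and, named after their values were seen, PFKP and LDHA were the other genes called higher, and EPAS1, a hypoxia-inducible factor subunit, the gene called lower (−0.16). ENO1 lost its call without untreated 2 or 3 or melphalan 1, 3 or 4, when quantile-normalized again and under cyclic loess (adjusted p from 0.0505 to 0.102), and BNIP3 without untreated 2 or 3 or melphalan 1 or 3 (from 0.055 to 0.0635). Without melphalan 2 the hypoxia and glycolysis list passed the test (adjusted p = 0.0477).

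Lists of p53 targets and apoptosis regulators were not called, while single members were. Of 61 p53 targets 9 rose, 1 fell and 51 did not pass (9 higher and 1 lower over the list alone). The camera test had adjusted p = 0.0612 in the upward direction, the mean log2 change was 0.03 and the median was −0.00480, which turned to 0.00431 after median centring, 0.00862 under cyclic loess and values up to 0.0115 without untreated 2, 3 or 4 or melphalan 1, 2 or 4. MDM2, the ubiquitin ligase that limits p53, rose by 0.31 (SE 0.06) from 10.49 ± 0.06 to 10.80 ± 0.13, PMAIP1, the BH3-only protein NOXA, by 0.33 (SE 0.03) and GDF15, a stress cytokine, by 0.28 (SE 0.04). TNFRSF10D was the member that fell. CDKN1A, the cell cycle inhibitor p21, differed by 0.11 (SE 0.04, adjusted p = 0.125) and was not called. The list passed the test without untreated 2 (adjusted p = 0.0461) and without melphalan 4 (0.0473). Of 27 apoptosis regulators 3 rose, 0 fell and 24 did not pass (camera adjusted p = 0.465; 3 higher and 2 lower over the list alone): MCL1 (0.48, SE 0.06), a BCL2 family protein that opposes cell death, CFLAR (0.42, SE 0.04), which blocks caspase 8, and BIRC2 (0.32, SE 0.06), an inhibitor of apoptosis. A dimmer probe set of CFLAR differed by 0.12.

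Lists of DNA repair and replication had medians of 0.02 to 0.06. Of 34 genes of crosslink repair and homologous recombination 1 rose, 0 fell and 33 did not pass (camera adjusted p = 0.129; 0 over the list alone). The median was 0.02, but 0.00414 without untreated 2 and −0.02 without the dimmest 50% of probe sets. The list passed the test when values were quantile-normalized again (median 0.04, adjusted p = 0.0327) and under cyclic loess (0.04 and 0.0349). The gene that rose was XRCC2 (0.20, SE 0.05), whose call was lost without untreated 1 (adjusted p = 0.0798), untreated 3 (0.0678) or melphalan 1, 2 or 3 (0.0831, 0.068 and 0.0708). Of 21 genes of nucleotide excision repair 2 rose, XAB2 (0.14, SE 0.03) and GTF2H1 (0.23, SE 0.06), 0 fell and 19 did not pass (median 0.04; 2 higher over the list alone). XAB2 lost its call without untreated 1 or 2 or melphalan 2 or 3 (adjusted p from 0.0561 to 0.0685), and GTF2H1 without untreated 1, 2 or 3 or melphalan 1 or 3 (from 0.0548 to 0.0784). Camera gave adjusted p = 0.0085 and adjusted p = 0.221 with an estimated correlation, and adjusted p was 0.106 among genes above the olfactory receptor level. Of 50 genes of DNA replication and S phase 7 rose, 0 fell and 43 did not pass (median 0.06; 10 higher and 0 lower over the list alone). They included DTL, an adaptor of the CUL4 ubiquitin ligase (0.25, SE 0.04), and PRIM1, a primase subunit (0.24, SE 0.05). For this list camera returned adjusted p = 1.49e-06 and adjusted p = 0.221 with an estimated correlation, and adjusted p was 0.0878 among genes above the olfactory receptor level. Of 61 genes of mitosis and G2/M 2 rose, ECT2 (0.27) and BUB3 (0.25), and 3 fell, KIF20A (−0.27) and, named after their values were seen, BIRC5 (−0.12) and TOP2A (−0.14), and 56 did not pass (camera adjusted p = 0.705; 2 higher and 1 lower over the list alone). BUB3 lost its call without untreated 1, 2 or 3 or melphalan 1 or 3 (adjusted p from 0.0509 to 0.0619). Among genes above the olfactory receptor level the mitosis and G2/M list was called lower (adjusted p = 0.0344).

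Histone and ribosomal protein genes have near-identical copies, so their probe sets may read several genes and their values are uncertain. Of 44 replication-dependent histone genes 8 rose, 1 fell and 35 did not pass (median 0.0270, and 0.0163 without untreated 3; 10 higher and 2 lower over the list alone), with H4C3 at 0.41 (SE 0.07), H2BC14 at 0.21 (SE 0.03) and, named after its value was seen, H2BC3 at −0.14. The camera test had adjusted p = 0.00923 and adjusted p = 0.353 with an estimated correlation, and the histone call was lost without the dimmest 50% of probe sets (adjusted p = 0.0816) and without melphalan 3 (0.0523). Of 42 cytosolic ribosomal protein genes 1 rose, RPL34 (0.20, SE 0.05), 0 fell and 41 did not pass (0 over the list alone). RPL34 lost its call when any array but untreated 1 or melphalan 2 was left out (adjusted p from 0.0526 to 0.0984), and a dimmer probe set of it differed by 0.05. The ribosomal median was 0.04, but −0.00128 when values were quantile-normalized again and 0.00646 with the direction of the test turned under cyclic loess, and both ended the call (adjusted p = 0.928 and 0.986). Camera gave adjusted p = 0.0223 and adjusted p = 0.353 with an estimated correlation, and the ribosomal call was also lost without untreated 3 (median 0.0221, adjusted p = 0.113) and without melphalan 4 (0.0547).

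Genes of endothelial identity were not called as a group. Of 43 genes of endothelial identity and junctions 9 rose, 4 fell and 30 did not pass (camera adjusted p = 0.203; 9 higher and 5 lower over the list alone). Their median was 0.000864, with −0.02 and −0.01 when values were quantile-normalized again or under cyclic loess, and from −0.00671 without melphalan 1 to 0.0186 without untreated 4. LYVE1, a hyaluronan receptor best known from lymphatic vessels, rose by 0.89 (SE 0.05) from 8.67 ± 0.11 to 9.57 ± 0.07, and S1PR1, a receptor for sphingosine 1-phosphate, by 0.25 (SE 0.04). FLT1, a receptor for VEGF, fell by 0.26 (SE 0.04), VWF, which tethers platelets, fell by 0.13 (SE 0.03), and MMRN1 (−0.20) and EMCN (−0.22), both named after their values were seen, completed the genes that fell. VWF kept its sign but lost its call without untreated 1, 3 or 4 (adjusted p = 0.0935, 0.0507 and 0.0689), without melphalan 1, 2, 3 or 4 (0.0515, 0.0788, 0.071 and 0.0905) and after median centring (0.051). PECAM1, an adhesion molecule of endothelial junctions, stood at 12.13 ± 0.02 and 12.17 ± 0.01 (difference 0.04, adjusted p = 0.402), and CDH5, the endothelial cadherin, at 11.75 ± 0.11 and 11.82 ± 0.07 (difference 0.08, adjusted p = 0.385). In the list of Notch, VEGF and angiopoietin signalling 5 of 42 rose, 2 fell and 35 did not pass (camera adjusted p = 0.283; 8 higher and 3 lower over the list alone). VEGFA, the main endothelial growth factor (0.18, SE 0.04), and SEMA3F, a repulsive guidance ligand (0.19, SE 0.03), rose with PDGFA, HEY2 and ACKR3, while SMAD7, an inhibitor of TGF-beta signalling (−0.21, SE 0.04), and EFNB2 (−0.13) fell; PDGFA, HEY2, ACKR3 and EFNB2 were named after their values were seen.

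Of 25 genes of coagulation and fibrinolysis 6 rose, 4 fell and 15 did not pass (7 higher and 6 lower over the list alone). The median was −0.02, but −0.000871 without untreated 2, −0.0110 without untreated 4, −0.0112 without melphalan 2, −0.01 after median centring or under cyclic loess, −0.00173 among genes above the olfactory receptor level and 0.00291 without the dimmest 50% of probe sets. The mean was 0.04 and the direction of the camera test was upward (adjusted p = 0.447). PLAT, the tissue plasminogen activator, rose by 0.51 (SE 0.05) and TFPI2, an inhibitor of serine proteases, by 0.49 (SE 0.05). ENTPD1, which breaks down extracellular ATP, fell by 0.32 (SE 0.04) together with VWF, PROCR (−0.15) and F8 (−0.14), of which PROCR and F8 were named after their values were seen. Of 19 genes of cholesterol biosynthesis SC5D rose (0.22, SE 0.05), HMGCS1 fell (−0.16, SE 0.04) and 17 did not pass (camera adjusted p = 0.66; 2 higher and 2 lower over the list alone). The call of HMGCS1 was lost without untreated 1, 2 or 4, without melphalan 2, 3 or 4 and under cyclic loess (adjusted p from 0.0577 to 0.0852), and that of SC5D without untreated 2 (0.0557).

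The extracellular matrix list and the markers of fibroblasts, retinal pigment epithelium and leukocytes were called lower. Of 49 genes of the matrix and TGF-beta targets 9 fell, 2 rose and 38 did not pass (median −0.05; 3 higher and 13 lower over the list alone). FBN1, the microfibril protein fibrillin-1, fell by 0.37 (SE 0.05) from 10.49 ± 0.10 to 10.12 ± 0.07 and COL8A1, a vascular collagen, fell by 0.28 (SE 0.04), while ADAMTS1 and, named after its value was seen, MMP10, a matrix metalloproteinase (0.29), rose. For this list camera returned adjusted p = 0.0337 and adjusted p = 0.476 with an estimated correlation. The matrix call was lost without untreated 3 (adjusted p = 0.0586), untreated 4 (0.138), melphalan 2 (0.0581) or melphalan 4 (0.1). Beside it, the fibroblast markers, which share 3 collagen genes with the matrix list, had a median of −0.07 and 2 of 12 fell, COL3A1 (−0.15, SE 0.04) and, named after its value was seen, FBLN1 (−0.13), while 10 did not pass (0 higher and 5 lower over the list alone). The camera test had adjusted p = 0.00448 for the fibroblast markers and adjusted p = 0.105 with an estimated correlation. COL3A1 lost its call without untreated 1 or 2 (adjusted p = 0.0657 and 0.0565) and without melphalan 2 or 4 (0.0535 and 0.0649). Markers of the retinal pigment epithelium had a median of −0.05 (−0.03 under cyclic loess) with 1 of 12 called, TTR (−0.14, SE 0.04), whose call was lost when any array but untreated 4 was left out (adjusted p from 0.0571 to 0.108). Camera gave adjusted p = 0.0463 for that list (0 higher and 3 lower over the list alone) and adjusted p = 0.277 with an estimated correlation. Its call was lost without untreated 2 (adjusted p = 0.0531), untreated 3 (0.063), melphalan 1 (0.0836) or melphalan 2 (0.0618). The leukocyte list (median −0.04 under cyclic loess) lost its call without untreated 3 (adjusted p = 0.0615) and melphalan 1 (0.0765), and 0 of its members passed over the list alone. The other marker lists were not called: pericytes and smooth muscle had MCAM higher (0.18) and TAGLN lower (−0.22) of 13 (camera adjusted p = 0.129; 1 higher and 1 lower over the list alone), astrocytes and Müller glia had SLC1A2 lower (−0.15) of 11 (0.447; 0 higher and 1 lower), and photoreceptors and retinal neurons had PRKCA higher (0.28) and STMN2 lower (−0.12) of 15 (0.203; 2 higher and 3 lower). SLC1A2 lost its call when any array but untreated 3 or melphalan 3 was left out (adjusted p from 0.0665 to 0.127). TAGLN and STMN2 were named after their values were seen. Endothelial cells express some of these markers themselves, such as MCAM and VIM (13.17 ± 0.04 and 13.21 ± 0.02). The brightest pericyte marker was RGS5 (11.41 ± 0.04 and 11.30 ± 0.12) and the brightest leukocyte marker LAPTM5 (10.24 ± 0.05 and 10.16 ± 0.02). Those of pigment epithelium and photoreceptors were KRT18 (10.16 ± 0.05 and 10.12 ± 0.04) and PDE6B (9.54 ± 0.07 and 9.47 ± 0.05). None of these was called, and which cells in the dishes gave their levels was not tested.

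**Figure D2:**
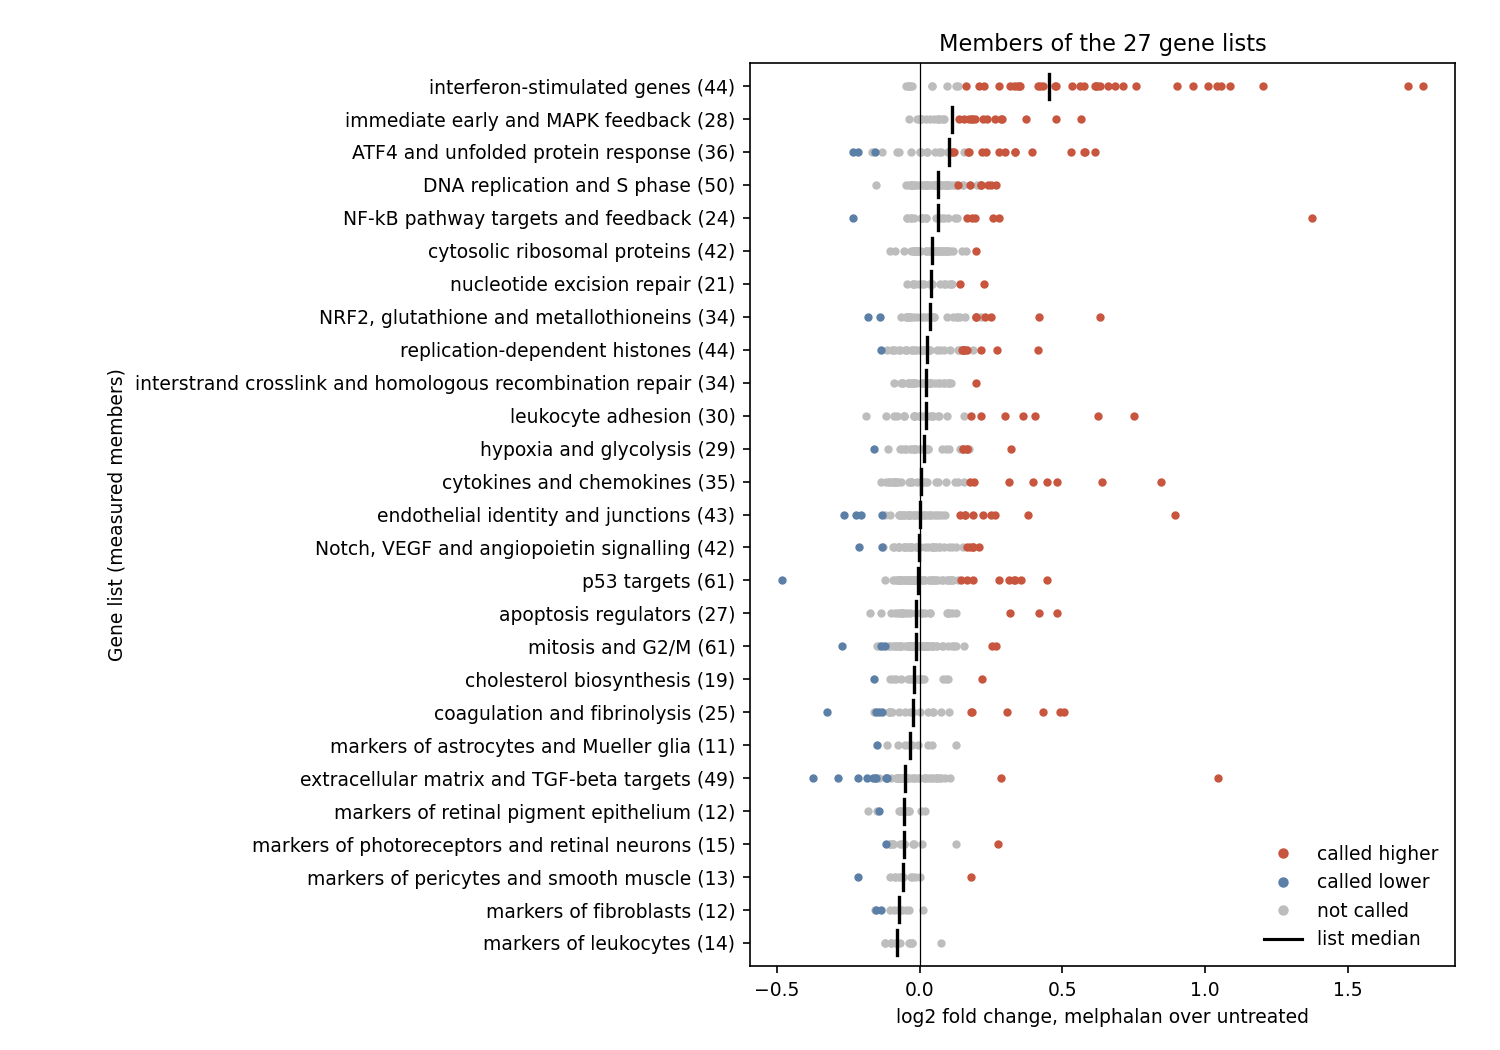
Log2 fold change (melphalan over untreated, horizontal axis) of each measured member of the 27 gene lists, 1 line per list with the number measured in brackets. Red points were called higher, blue points lower and grey points neither, and the black bar is the list median, from 0.45 for the interferon-stimulated genes to −0.08 for the leukocyte markers.

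**Figure D3:**
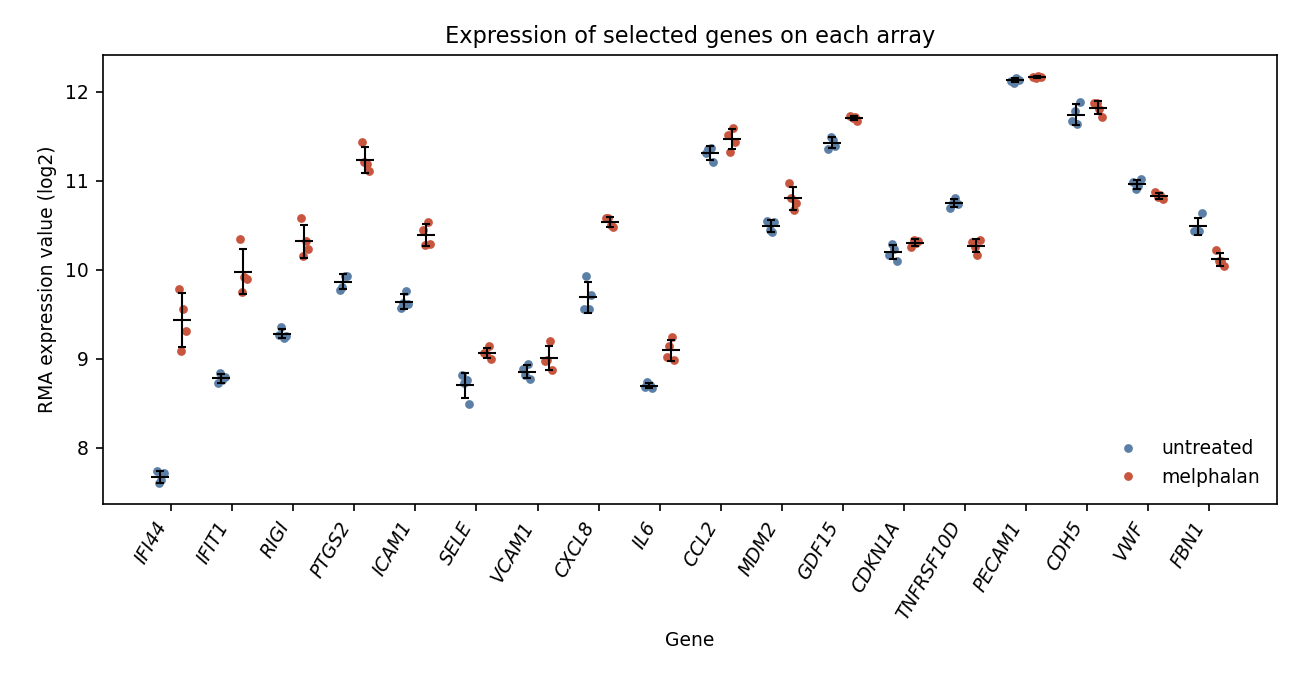
Log2 RMA value (vertical axis) of 18 genes on each of the 4 untreated (blue) and 4 melphalan-treated (red) arrays, with black bars for mean and SD. The treated arrays lie above all untreated arrays for IFI44, IFIT1, RIGI, PTGS2, ICAM1, SELE, CXCL8, IL6, MDM2 and GDF15, below all of them for TNFRSF10D, VWF and FBN1, and overlap with them for VCAM1, CCL2, CDKN1A, PECAM1 and CDH5.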

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

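The tests on the leukocyte markers, on the median of the olfactory receptor genes and on that median against genes of the same level were chosen only after the result was seen. The cut-offs of the scaling and single-array tests were set from the interferon list's own median and count. Further tests below that use olfactory receptor genes also rest on a choice made after the data were seen.

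Single arrays stood apart by a gap above Dixon's 95% critical value for 4 arrays, as a share of the group's range, in 10 of 244 group tests, where chance gives about 5%. The gap was 0.903 for CXCL11 (melphalan 1 at 8.53, the others at 8.18 to 8.21), 0.942 for SC5D (melphalan 1 at 9.55, the others at 9.38 to 9.39), 0.854 for PRKCA (melphalan 1 at 9.65, the others at 9.56 to 9.57) and 0.830 for GTF2H1 (melphalan 1 at 9.64, the others at 9.40 to 9.44). It was 0.842 for ENO1 (melphalan 2 at 12.03, the others at 12.07), 0.977 for FBN1 (untreated 4 at 10.64, the others at 10.44) and 0.861 for SAMD9 (untreated 1 at 8.55, the others at 8.59). Of the list means, each relative to the genes' untreated means, the gap was 0.923 for hypoxia and glycolysis (untreated 4 highest at 0.02, the others at −0.01 to −0.00492), 0.8294 for cytosolic ribosomal proteins (melphalan 2 lowest at −0.00150, the others at 0.05 to 0.06) and 0.860 for astrocyte and Müller glia markers (melphalan 3 highest at −0.01, the others at −0.03). Of the 12083 probe sets without a name here, 221 were called (91 higher, 130 lower), and of the 1754 paired with several genes 40 were called (31 higher, 9 lower).

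The rise of interferon-stimulated genes was weighed first. The count of 34 members called higher was reached by 1 of the 35 splits of the 8 arrays, the real one. The highest other split called 0. This argues against chance but cannot exclude it, since 35 splits give no share below 1 of 35. That 0 is not particular to this list, as no other split called any gene changed. A scaling difference between arrays was set against 3 other scalings, under which the list's median stayed at 0.451 or more. That test could hardly come out otherwise, since the deposited values were already normalized together. The other scalings took the median of all genes from −0.0190 to no higher than −0.00696. The tables argue against 1 deviating array, since at least 33 members were called whichever array was left out. They also argue against leukocyte RNA in the treated dishes as the source of the rise. Of the 14 leukocyte markers 0 were called higher, and their median, less that of the olfactory receptor genes, was 0.00150. Over left-out arrays and other scalings it was at most 0.0206. The 24 interferon-stimulated genes in the dim range gave 0.524 (at least 0.480), at a median level of 8.59 against 8.57 for the markers. An effect of leukocytes on the endothelial cells was not tested. An effect of melphalan stays open with no mechanism tested, and so do dish handling and culture infection, which the labels do not describe. For scale, the count of 1658 changed genes was reached by 1 of the 35 splits and the highest other called 0, and 15 lists were called by 1 of the 35 while the highest other, with 3 treated arrays on a side, called 13 and the 18 splits with 2 arrays of each group on each side called 0 to 4.

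The lower values of other cell types' markers and of dim genes were weighed second. Olfactory receptor genes had a median of −0.0800. A downward shift set by level alone is argued against as its whole cause, since its difference from other genes of the same level was −0.0470. That difference was −0.05 to −0.04 over left-out arrays and other scalings. In the 18 splits with 2 arrays of each group on each side it was at most 0.03 in size. Of the 5 marker lists without a bright majority, 2 lay inside the central 95% of lists matched on level. Those of fibroblasts, leukocytes and pericytes lay below it, at percentiles 1.05, 0.45 and 1.81. Short genes alone are argued against, since the olfactory receptor median lay at percentile 0 of random genes matched on level and length. A downward shift of dim probe sets on the treated arrays that follows more than level cannot be told apart from true change in dim genes, and a common downward shift of genes these cells do not use stays open, since the 51 dim markers (median −0.07) lay at percentile 92.4 of random sets of olfactory receptor genes. Fewer cells of other types in the treated dishes also stays open, since the 26 bright markers (median −0.04, 2 called higher and 2 lower) lay at percentile 1.46 of genes matched on level, a value that could equally come from change within the endothelial cells.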

How the results depend on the processing

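The fit on genes above the olfactory receptor level was chosen after the data were seen, all other alternatives before; where a call changed, the cause was not tested unless stated. Of the 1654 values of 95 named genes under alternatives, 1548 kept sign and call, 91 lost the call, 15 gained it and 0 changed sign; 15 of 78 called genes lost the call somewhere, 5 of them only when an array was left out. No gene called in both fits changed sign under any of the 18 refits. The interferon, immediate early, ATF4, NF-kB and fibroblast lists lost their calls only with an estimated correlation. Signal over background limits the dim genes, where most lower calls lie. The labels do not say whether the replicate numbers pair the dishes. Deviations of same-numbered arrays correlated at 0.02, −0.02, 0.05 and −0.30, which shows no common pairing effect but cannot settle the design. Those of untreated 4 and melphalan 1 correlated at 0.46. With the replicate number as a block, which spends degrees of freedom, limma called 901 higher and 231 lower, and the cytokine list (0.00608) was no longer called.

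Against 1211 higher and 447 lower, all probe sets counted singly gave 883 changed (635 higher, 248 lower), an adjusted p below 0.01 gave 471 (400 and 71) and a 1.5-fold minimum 38 (37 and 1), the last 2 of which can only remove calls. The number lower was 279 under cyclic loess, 267 without the dimmest 50%, 700 with array weights and 174 among genes above the olfactory receptor level, where fewer genes were tested. Higher calls were 73.0% of all calls, 66.3% with array weights, 71.3% without untreated 3, 81.8% without the dimmest 50% and 84.8% above the olfactory receptor level. Leaving out 1 array gave 858 to 1912 changed, 674 to 1392 higher and 184 to 520 lower genes.

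The list values are median log2 changes. With an estimated correlation all 15 list calls were lost at unchanged medians: excision repair 0.0410, DNA replication 0.0649, histones 0.0270, adhesion 0.0224, cytokines 0.00608, NF-kB 0.0634, interferon 0.453, matrix −0.0498, ATF4 0.102, NRF2 0.0376, immediate early 0.113, ribosomal 0.0433, and markers of fibroblasts −0.0731, pigment epithelium −0.0541 and leukocytes −0.0785. Under fry, histones (0.0270), matrix (−0.0498), ribosomal proteins (0.0433) and leukocyte markers (−0.0785) lost their calls, and p53 targets (−0.00480, in the upward direction) and photoreceptor markers (−0.0553) gained one. Quantile normalization repeated ended the calls of adhesion (0.00338), NRF2 (0.0491), ribosomal proteins (−0.00128), pigment epithelium (−0.0422) and leukocyte markers (−0.0524) and gave one to crosslink repair (0.0355). Cyclic loess ended those of adhesion (0.00810), NRF2 (0.0578), pigment epithelium (−0.0329), leukocyte markers (−0.0449) and ribosomal proteins (0.00646, with the test direction turned and adjusted p = 0.986) and gave one to crosslink repair (0.0442). Median centring ended the cytokine call (0.0152), and the mean of probe sets those of cytokines (0.00608) and pigment epithelium (−0.0541). Without the dimmest 33.3%, cytokines (0.0121), NRF2 (0.0347), ribosomal proteins (0.0433), pigment epithelium (−0.0439) and leukocyte markers (−0.0566) lost their calls, and without the dimmest 50% histones (0.0337), cytokines (0.0417), ribosomal proteins (0.0422), pigment epithelium (−0.0524) and leukocyte markers (−0.0566) did. Array weights ended the calls of cytokines (−0.000790), ribosomal proteins (0.0384), pigment epithelium (−0.0524) and leukocyte markers (−0.0626). Above the olfactory receptor level excision repair (0.0420), DNA replication (0.0568), adhesion (0.0230), cytokines (0.0930), NRF2 (0.0727), ribosomal proteins (0.0429) and leukocyte markers (−0.0839) lost their calls, with fewer members tested, and mitosis was called lower (−0.0235). In that fit histones (0.108), NF-kB (0.126) and immediate early genes (0.175) kept their calls at larger medians than in the main fit. With 1 array left out, medians ranged from −0.00553 to 0.0115 for p53 targets, 0.0163 to 0.0367 for histones, 0.0378 to 0.0676 for NF-kB, 0.0225 to 0.0433 for NRF2, 0.00414 to 0.0343 for crosslink repair, −0.00272 to 0.0172 for cytokines, −0.0651 to −0.0413 for matrix, −0.000369 to 0.0241 for hypoxia, 0.0221 to 0.0549 for ribosomal proteins, −0.0680 to −0.0477 for pigment epithelium and −0.0889 to −0.0541 for leukocyte markers.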

Other observations

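The lists in this first paragraph were added after the data were seen and are not independent evidence. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose in 13 of 19 cases with 0 lower (median 0.26), led by GARS1 (0.51, SE 0.05), TARS1 (0.39, SE 0.05) and SARS1 (0.34, SE 0.05). Camera gave adjusted p = 3.91e-14 over the 7 added lists and adjusted p = 0.0635 with an estimated correlation. Of 24 amino acid transporters 9 rose and 0 fell, among them SLC7A1, a carrier of cationic amino acids (0.49, SE 0.04), and SLC38A1, a glutamine carrier (0.51, SE 0.05), with camera adjusted p = 3.55e-06 and adjusted p = 0.038 with an estimated correlation. Adjusted p-values in this paragraph cover the 7 added lists only, so they cannot be set against those of the planned lists. By camera with an estimated correlation, unadjusted p was 0.0108 for the transporters and 0.00654 for the olfactory receptor genes. It was smaller, 0.00421, for the interferon-stimulated genes, which that test did not call among the planned lists. Of 23 folding enzymes and chaperones of the endoplasmic reticulum 4 fell, HSP90B1 (−0.23), HYOU1 (−0.16), PDIA4 (−0.21) and CALR (−0.16), 1 rose, ERO1A (0.22), and 18 did not pass. The median of this list and that of all genes were both −0.02, and it was not called (camera adjusted p = 0.0782, and adjusted p = 0.409 with an estimated correlation), though 7 alternatives called it lower, among them the fits without untreated 2 and without melphalan 1. Of 12 genes of prostanoid synthesis 3 rose, PTGS2 (1.37), PLA2G4A, which frees arachidonic acid (0.20, SE 0.04), and PTGIS, the prostacyclin synthase (0.18, SE 0.04), while the list's median was −0.04 and its camera test upward (adjusted p = 0.337, and adjusted p = 0.409 with an estimated correlation). Of 20 FOXO targets 4 fell and 0 rose: SESN3 (−0.56), YPEL2 (−0.22), TXNIP, an inhibitor of thioredoxin (−0.17), and FOXO3 (−0.14). Camera gave adjusted p = 0.0103 for the FOXO targets and adjusted p = 0.0614 with an estimated correlation. The FOXO median was −0.07, near the −0.08 of the olfactory receptor genes, and 9 of the 20 members lay above the olfactory receptor level. Olfactory receptor genes were called lower as a list (camera adjusted p = 3.91e-14, and adjusted p = 0.038 with an estimated correlation), and 192 small nucleolar and Cajal body RNAs had 10 higher and 2 lower (camera adjusted p = 0.0211, and adjusted p = 0.537 with an estimated correlation), with untreated 3 at a mean of 7.76 and the other arrays at 7.94 to 8.01.

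A hypothesis written before the data were examined was that DNA adducts, which block transcription, lower long genes more than short ones. Among 8744 protein-coding genes above the median level, the median log2 change was 0.0250 in the longest 10%, 0.0414 in the next longest and −0.0352 in the shortest. The longest 10% had 137 genes called higher and 28 lower, the most lower calls of any 10%. Its median minus that of the shortest 10% was 0.0602, so long genes were the higher ones by this measure and the predicted fall was not seen. That difference ranged from 0.04 to 0.08 over left-out arrays and other scalings, against a root mean square of 0.03 and a largest absolute value of 0.0566 in the 18 splits with 2 arrays of each group on each side, and 3 splits with 3 arrays of 1 group on a side gave 0.0757, 0.0747 and 0.0693, more than the real split. A trend with gene length between arrays that does not follow the treatment stays open. Spearman's rho across genes was 0.27 (genes are not independent replicates). Of the 35 splits 10, the real one included, gave a rho as large in absolute value, and the highest other was 0.368.

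The count of p53 targets called lower was a test chosen only after the result was seen. The test on brighter members uses the olfactory receptor genes, which were added after the data were seen. For the p53 targets, the members brighter than the olfactory receptor level had a median of −0.000975, and 1 member was called lower. By splits of the 8 arrays, the real split alone gave the most extreme camera p for interferon-stimulated genes, immediate early genes and ATF4 targets. Counting the real split itself, as extreme a p came from 2 of 35 splits for NF-kB targets. The count was 3 for DNA replication, NRF2 targets, cytokines, leukocyte adhesion, fibroblast markers and retinal pigment epithelium markers. It was 4 for nucleotide excision repair, 8 for histones and leukocyte markers, 12 for the matrix list and 13 for ribosomal proteins.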
